A study of Mus musculus with 9 samples.

How the data were processed

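Gene expression was measured on 9 Affymetrix Mouse Genome 430 2.0 arrays, each for 1 labelled passage of D3-pOct4 mouse embryonic stem cells in 1 condition. Signal intensities were deposited on a linear scale; per the labels and the design text, they came from GeneChip Operating System version 1.4.0.036 with global scaling, and the submitters' processing notes name MAS5. The 2 percent trimmed mean of each deposited column was 100, so every array carries the same scaling target. Detection calls and scanner files were not used here. The table holds 45101 probe sets with intensities from 0.0144 to 17201.

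Values were turned to log2(signal + 3), the pseudocount being the 20th percentile of the table rounded to a whole number. A fold change is on that scale and understates the change of dim probe sets. The 64 control probe sets were left out of the tests and read as checks of RNA and labelling. A probe set was tested if it lay at or above the 40th percentile of its array on at least 3 of the 9 arrays, which left 29811. No further normalization was applied.

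Probe sets were named from the platform annotation, in which 34945 probe sets carry 1 gene symbol, 932 carry several and 9160 carry none; none was named from several. Symbols were checked through Entrez identifiers against RefSeq genes of GRCm38.p6, where 34754 matched and 0 symbols changed. The tested set covered 13376 genes. For a gene with several tested probe sets, the one with the highest mean signal over all arrays stood for the gene. Genome coordinates were not used here.

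The 3 comparisons were made in 1 fit over all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with group as the only term. P-values were adjusted by Benjamini-Hochberg over all tested probe sets, at a threshold of 0.05. The groups share replicate numbers, which stand for passages 31, 33 and 34, and a fit with that number as a block was an alternative.

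The 26 gene lists, fixed before the data were examined, were tested with limma's camera at a preset inter-gene correlation of 0.01. Their p-values were adjusted over the 26 lists. Camera with an estimated correlation and fry were run beside it. The estimated correlation exceeded the preset for 24 of the 26 lists, with a median of 0.154 and a highest value of 0.736. Correlations between list means used exact permutation tests in scipy 1.17.1.

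The genes named in the text follow a rule set before the data were examined. It always takes 12 genes of pluripotency, LIF response and early lineages, of which T (brachyury) has no probe set named for it alone and is not analysed here. It adds the genes called, or the 10 with the smallest p where none is, and the called members of each list, or the 2 brightest of a list the text describes where none is; the lists so described were picked after their results were seen. The position of the donor arrays between the other groups was computed on 200 genes chosen in the other 2 passages. Chance values of calls shared by the comparisons against LIF came from 100 simulated sets of unchanged groups.

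The alternatives were the pseudocount, the filter, quantile normalization or median centring, the variance trend, the arrays in the fit, the replicate block, the kind of probe set, a 2-fold minimum and the omission of each array in turn. After the data were seen, fits were added without arrays that raised doubt and with array brightness as a block. The fit was tested on simulated data for the comparison of no LIF with LIF, over 29811 probe sets. At the observed spread it recovered 2%, 24%, 48% and 72% of 50 probe sets each changed by 1, 2, 3 and 4 on the log2 scale, with 3 false calls. At a spread divided by 3 it recovered 78%, 98%, 98% and 100%, with 11 false calls. The spread between arrays, together with their number of 3 per group, limits the precision. The median standard error of a log2 difference was 0.5.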

Results

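Mouse embryonic stem cells of the D3-pOct4 line were kept for 7 days in 3 conditions. One group received 1000 U/ml of leukemia inhibitory factor (LIF), the cytokine that holds these cells undifferentiated through the transcription factor STAT3. A second group had no LIF. The third had no LIF and 2 µM DETA/NO, a compound that releases nitric oxide slowly. Each group has 3 arrays, replicates 1, 2 and 3, grown from passages 31, 33 and 34. The labels do not say more about how far the cultures were separate, so p-values measure the spread between these arrays.

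The median signal of an array ran from 13.9 to 23.3. It was 20.8 to 23.3 on LIF replicate 1 and on replicates 1 and 2 with the donor, and 13.9 to 17.8 on the other 6 arrays. These 3 arrays are called brighter for their median alone, as every array has a trimmed mean of 100. Their 40th percentile was 12.9 to 14.6, against 8.17 to 10.4 elsewhere. Their 90th percentile was not higher, at 328.6 to 336.7 against 334.2 to 342.6, so only the lower part of their signals was raised. The same 3 brighter arrays had the highest signals of the Dap poly-A spike, 1320 to 2422, against 250 to 881 elsewhere. The hybridization spike BioB was highest there too, at 225.4 to 279.7 against 128.4 to 200.5. The ratio of Dap to the hybridization spike BioC did not part them, at 1.36 to 2.55 against 0.438 to 1.59. The ratio of 3' to 5' signal was 1.52 to 3.15 for beta-actin, highest on no LIF replicate 3, and 0.812 to 0.955 for Gapdh.

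Socs3, a STAT3 target that dampens LIF signalling, was read first on every array. Its signal was 3213 and 1794 on LIF replicates 1 and 3, and 102 and 330 on no LIF replicates 1 and 3. On the array labelled LIF replicate 2 it was 282, and on the array labelled no LIF replicate 2 it was 3054. With the donor it was 95.8, 405 and 127 in replicates 1 to 3. Klf4, a naive pluripotency factor, read 2482, 1062 and 1863 with LIF, 197, 2542 and 698 without, and 1368, 625 and 233 with the donor. Fgf5, a marker of the primed epiblast, read 0.888, 56.6 and 0.71 with LIF, 521, 0.576 and 19.1 without, and 44.1, 82.6 and 567 with the donor. Both replicate 2 arrays of the groups with and without LIF thus go against their labels for Socs3, and every direction below is drawn with the arrays as labelled.

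**Figure D1:**
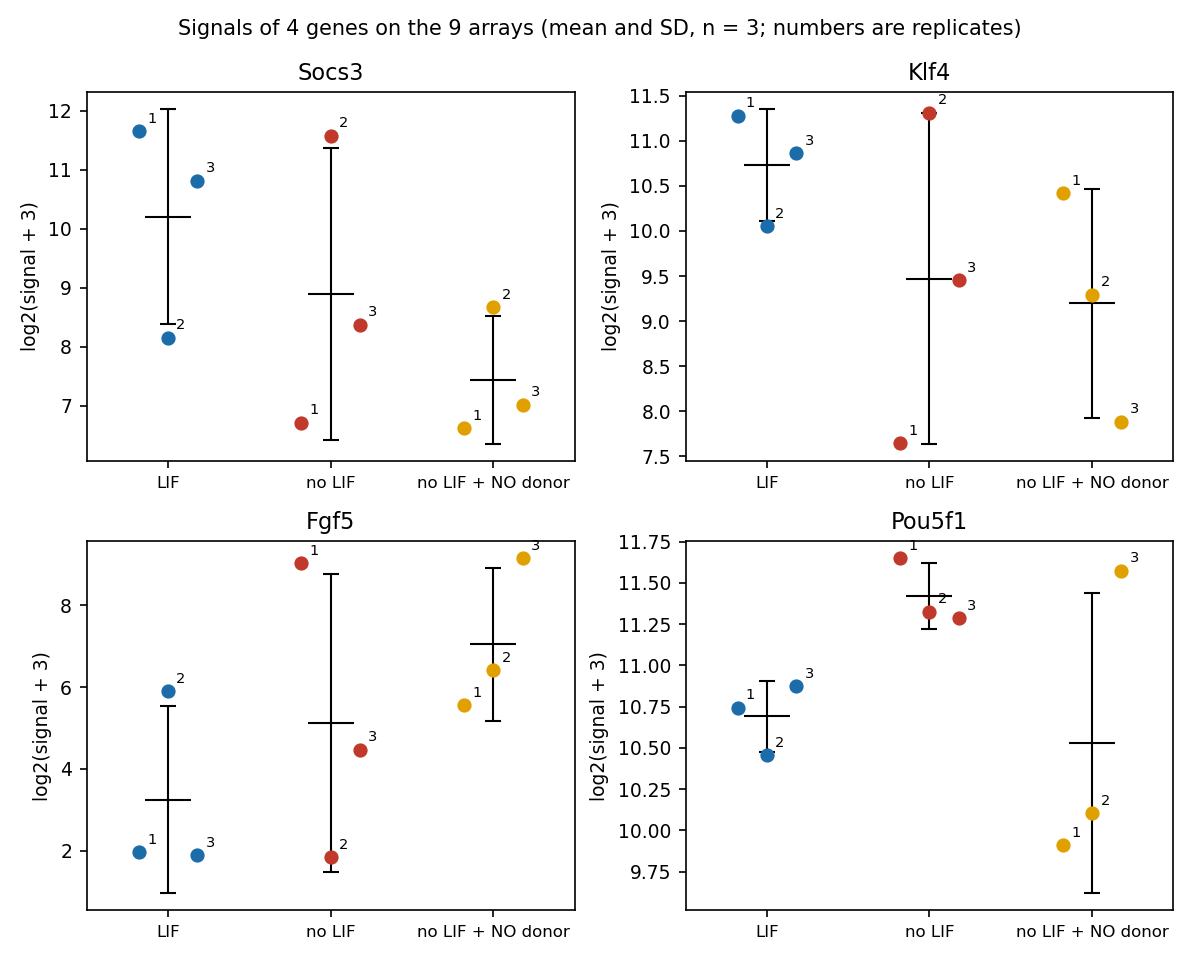
Signals of Socs3, Klf4, Fgf5 and Pou5f1 as log2(signal + 3) on the vertical axis, by group; points are arrays numbered by replicate, and bars give the mean and SD of 3 arrays. Socs3 is high on LIF replicates 1 and 3 and on the array labelled no LIF replicate 2, and Fgf5 is low on the same 3 arrays.

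The groups did not set the arrays apart. The mean correlation of log2 signals was 0.88 within groups and 0.887 between groups, and 161 of the 280 ways to part 9 arrays into 3 sets of 3 gave a mean within sets as high (exact p = 0.575). By passage the values were 0.878 and 0.888 (exact p = 0.664). Of the 9 arrays, 0 correlated best with an array of its own group. The closest pair was no LIF replicate 1 and replicate 3 with the donor, at r = 0.977, from different groups and passages, named the alike pair below. Over the brightest 25% of probe sets the SD of their log2 difference was 0.198, against 0.532 for the next closest of the 36 pairs and 0.601 to 1.27 for pairs within a group.

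**Figure D2:**
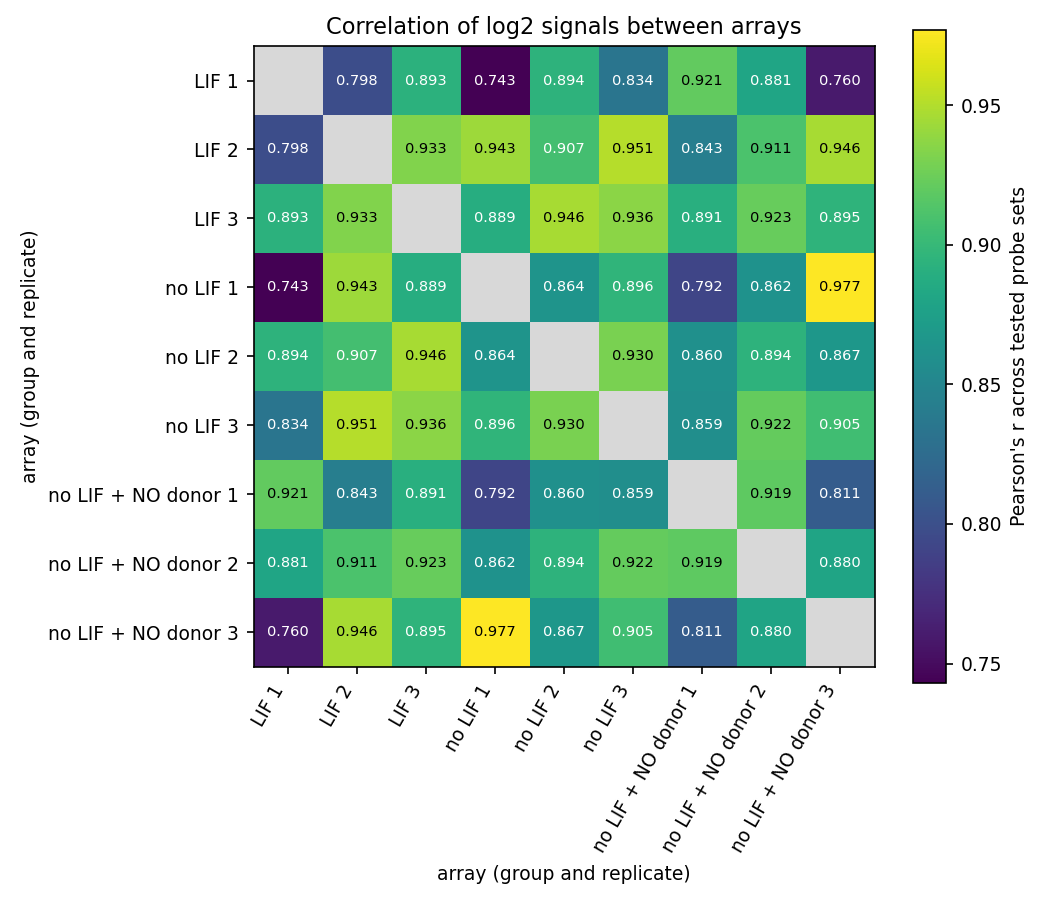
Pearson's r of log2 signals across the tested probe sets for each pair of the 9 arrays, named by group and replicate on both axes, with the scale at the right. The highest value, 0.977, joins no LIF replicate 1 and donor replicate 3, and the lowest, 0.743, joins LIF replicate 1 and no LIF replicate 1.

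The first comparison asks what 7 days without LIF do to these cells. No gene passed the test. Gata6 and Tbx3, which act in extraembryonic endoderm and in naive stem cells, had signals of 59.9 ± 41.5 and 309 ± 300 without LIF against 211 ± 200 and 645 ± 93.1 with it (SD, n = 3). Their log2 differences were -1.52 (SE 0.66) and -1.63 (SE 0.88), with limma adjusted p = 0.973 for both. The pluripotency factor Pou5f1 read 2754 ± 397 without LIF and 1662 ± 240 with it (SD, n = 3), a log2 difference of 0.73 (SE 0.41). It was higher without LIF in 3 of 3 passages.

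The remaining genes of the fixed set also missed the threshold. Log2 differences without LIF were -1.32 for Socs3 (SE 1.19), -0.87 for Stat3 (SE 0.6), -1.26 for Klf4 (SE 0.86), -0.6 for Esrrb (SE 0.72), -0.25 for Zfp42 (SE 0.37), -0.07 for Sox2 (SE 0.36), 0.47 for Nanog (SE 0.49) and 1.86 for Fgf5 (SE 1.69). Of 3 other probe sets of Stat3, 2 took its sign. The 10 genes with the smallest p did not pass either. They were Rgs16, Dmrt1, Gnmt, Kcnh8 and Col22a1, higher by 2.26 to 1.68, and Cd300a, Flrt3, Depp1, 2900092C05Rik and Adam33, at -2 to -1.65 on the log2 scale. Cd300a had the smallest p, 6.4e-04 in limma, at a signal of 1.46 ± 0.313 without LIF and 15.4 ± 6.04 with it (SD, n = 3). Array medians were 13.9 to 23.3, so even its higher mean is a dim signal. Dmrt1, a regulator of germ cells, read 232 ± 66.6 without LIF and 61.9 ± 45.9 with it (SD, n = 3).

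Gene lists were compared next, with camera at the preset correlation, which called 14, 10 and 8 of the 26 lists in the 3 comparisons. With an estimated correlation camera called 0, 0 and 0, and fry called 0, 0 and 0, with smallest adjusted p of 0.493, 0.528 and 0.709. Primitive and parietal endoderm markers lay lower without LIF: 17 of 19 were lower and the median log2 difference was -0.94 (adjusted p = 8.14e-06; adjusted p = 0.365 with an estimated correlation). Its brightest members were Sparc at -0.8 and Serpinh1 at -1.1, a secreted matrix protein and a collagen chaperone of the endoplasmic reticulum; of 2 other probe sets of Sparc, 1 took its sign. LIF/STAT3 targets were lower in 15 of 19 with a median of -0.85 (adjusted p = 0.0107; 0.365 as an adjusted p with an estimated correlation). Among these targets the adhesion molecule Icam1 stood at -0.86 and the kinase Pim3 at -0.05, the sign of 1 of 2 other probe sets of Pim3. Further lists lay lower: endothelial and blood markers (12 of 14, adjusted p = 0.00638), Hox genes (9 of 10, 0.00298), BMP and TGF-beta targets (12 of 15, 0.0062), ERK targets (12 of 15, 0.02) and visceral and definitive endoderm (8 of 12, 0.0326). With an estimated correlation each of these 5 had an adjusted p = 0.365. Of 34 listed Hox genes only 10 were tested, and their list mean was -3.29 to -2.14 relative to all genes. The brightest, Hoxa5 and Hoxa9, read 30.1 and 7.65 without LIF and 33.8 and 19 with it. The Hox list thus rests on dim signals.

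Other lists lay higher without LIF. Oxidative phosphorylation was higher in 25 of 26 members with a median of 0.26 (adjusted p = 8.53e-05), oxidative stress and NRF2 genes in 18 of 19 with 0.35 (4.32e-04), cell cycle genes in 24 of 27 with 0.29 (0.00146) and germline genes in 9 of 11 with 0.65 (0.00304). With an estimated correlation these 4 had an adjusted p = 0.365. Formative and primed epiblast markers were higher in 13 of 17 with a median of 0.59 (adjusted p = 0.02; adjusted p = 0.554 with an estimated correlation), with Dnmt3b at 1.01 and Nodal at -0.23. Hypoxia and glycolysis genes were higher in 15 of 23 (adjusted p = 0.0236; adjusted p = 0.571 with an estimated correlation), and pro-apoptotic genes in 16 of 17 (adjusted p = 0.044; adjusted p = 0.554 with an estimated correlation). The other 12 lists had an adjusted p from 0.0897 for p53 targets to 0.754. They include naive pluripotency, with 17 of 29 lower (adjusted p = 0.194), cardiac and smooth muscle (0.203), fibroblast and mesenchyme (0.258), trophoblast (0.126), WNT targets (0.258), the unfolded protein and heat shock response (0.542) and the nitric oxide and cGMP pathway (0.509). The median and the test took opposite signs for primitive streak (median 0.19), neuroectoderm (0.06), interferon response (0.02) and anti-apoptotic genes (-0.08).

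Several of these lists differed between passages or settings. Median log2 differences at passages 31, 33 and 34 were -2.08, 0.68 and -0.48 for STAT3 targets, 2.24, -1.86 and 1.02 for primed markers, -1.54, 0.42 and -1.39 for parietal endoderm and -1.06, 1.1 and 0.37 for glycolysis. Without the alike pair, STAT3 targets had an adjusted p = 0.344 (median -0.23), primed markers 0.546 (-0.09), visceral endoderm 0.197 (-0.36) and pro-apoptotic genes 0.141 (0.23), and parietal endoderm passed at 0.00353 (-0.34). With brightness as a block, STAT3 targets had 0.0519 (-0.44), primed markers 0.0619 (0.34), visceral endoderm 0.1 (-0.34), endothelial markers 0.0704 (-0.37) and pro-apoptotic genes 0.262 (0.1). These lists also missed the threshold within the 6 dimmer arrays, at 0.0584 to 0.351. After quantile normalization, oxidative phosphorylation and cell cycle each had an adjusted p = 0.359 (medians 0.14 and 0.17), glycolysis 0.505 (0.16), and oxidative stress, primed markers and visceral endoderm 0.0527 (0.21, 0.72 and -0.46), and naive pluripotency passed at 0.00186 (-0.29). In all 10 lists passed there, so naive pluripotency was not the only list gained. Without both replicate 2 arrays, which leaves 2 arrays with and 2 without LIF, calls ended for BMP and TGF-beta targets (median -0.41, adjusted p = 0.388), ERK targets (-0.4, 0.46), Hox genes (-0.33, 0.228), germline genes (0.38, 0.51), cell cycle (0.25, 0.239), oxidative phosphorylation (0.3, 0.228) and glycolysis, whose median turned to -0.24 (0.385). STAT3 targets, primed markers and parietal endoderm then had larger medians of -1.5, 1.63 and -1.58. Leaving out 1 array moved Dnmt3b to between 0.16 and 1.79, Serpinh1 to between -1.64 and -0.34, Sparc to between -1.22 and -0.27, Socs3 to between -2.66 and -0.23, Klf4 to between -2.19 and -0.35, Tbx3 to between -2.44 and -0.73 and Gata6 to between -2.13 and -0.77.

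Of 29811 probe sets limma called 0, with 459 at an unadjusted p under 0.05 (1.54%, 82 higher and 377 lower) and a smallest adjusted p of 0.973; called members of the lists were 0 over all genes and 0 adjusted over the list alone. The 459 became 269, 1719 or 243 without LIF replicate 1, 2 or 3 and 738 without donor replicate 3, and without both replicate 2 arrays it was 2326 with 0 calls.

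**Figure D3:**
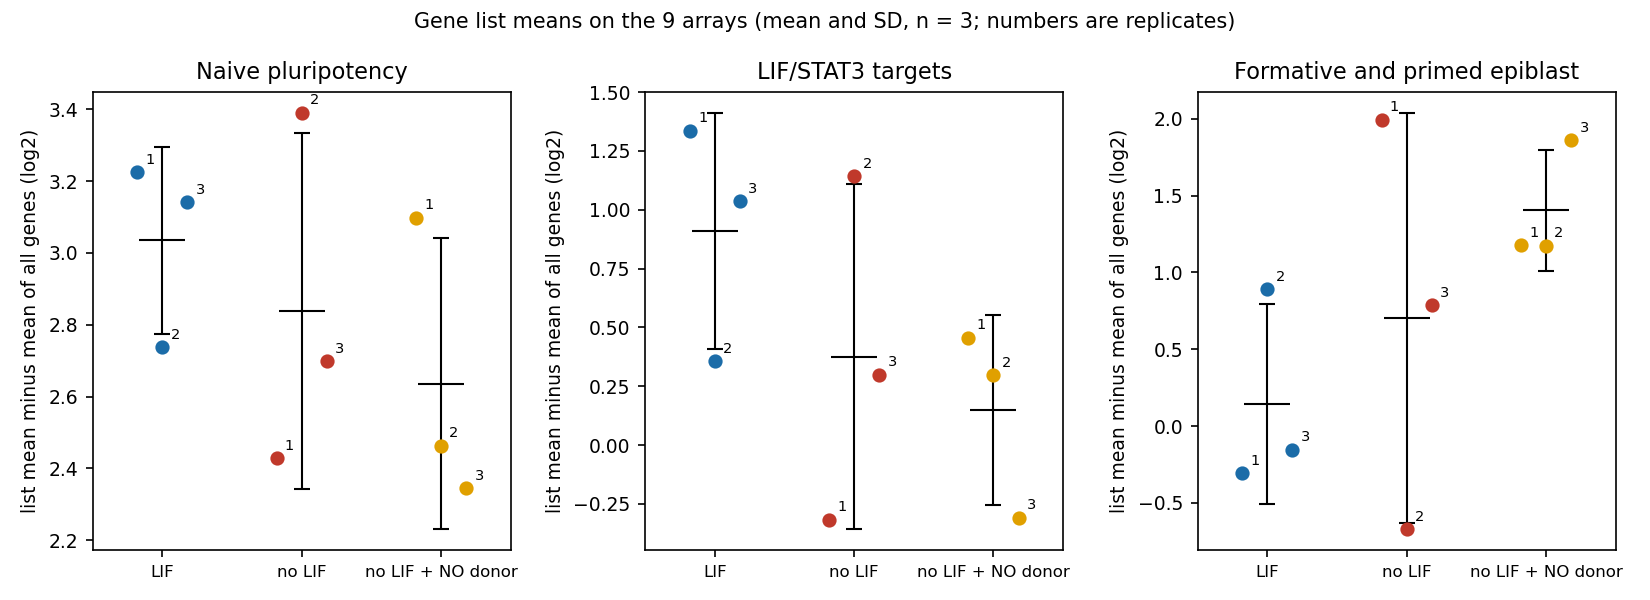
Mean log2 signal of 3 gene lists relative to the mean of all genes tested (vertical axis), by group; points are arrays numbered by replicate, and bars give the mean and SD of 3 arrays. On the array labelled no LIF replicate 2 the naive list is at 3.39 and the primed list at -0.672, the extremes of the 9 arrays.

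The second comparison asks what the nitric oxide donor adds in cells without LIF. No gene passed the test. Pou5f1 read 1699 ± 1167 with the donor and 2754 ± 397 without it (SD, n = 3), a log2 difference of -0.89 (SE 0.41; limma adjusted p = 0.929). Its signal was 958 and 1096 on donor replicates 1 and 2, and 3044 on replicate 3. Nanog, another core pluripotency factor, read 671 ± 347 and 1045 ± 263 (SD, n = 3), at -0.79 (SE 0.49). Fgf5 differed by 1.93 (SE 1.69) and Socs3 by -1.45 (SE 1.19).

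The other genes of the fixed set lay between -0.46 for Stat3 and 0.08 for Tbx3. Among the 10 genes with the smallest p, Tes3-ps, Serpina10, Cd300a, Faxc and C130075A20Rik were higher with the donor by 1.98 to 1.61, and Pgam2, Alppl2, Klhl10, Ptprcap and A330009N23Rik stood at -2.36 to -1.56 on the log2 scale. Other probe sets took the sign given in 1 of 3 cases for Faxc and Stat3 and in 1 of 2 for Esrrb and Tbx3. Alppl2, an alkaline phosphatase, read 1.57 ± 0.336 with the donor and 17.1 ± 4.21 without it (SD, n = 3), the higher mean being within the array medians of 13.9 to 23.3. Pgam2, a muscle phosphoglycerate mutase, read 7.51 ± 7.88 and 47.8 ± 27.7 (SD, n = 3).

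Of the 26 lists, 6 lay lower with the donor. Oxidative phosphorylation genes were lower in 26 of 26 members with a median of -0.59 (adjusted p = 9.8e-11; adjusted p = 0.461 with an estimated correlation), Atp5b standing at -0.41 and Cox4i1 at -0.21. Hypoxia and glycolysis genes were lower in 21 of 23 with a median of -0.84 (adjusted p = 1.5e-08; adjusted p = 0.461 with an estimated correlation), and oxidative stress and NRF2 genes in 17 of 19 with -0.73 (8.32e-08; adjusted p = 0.461 with an estimated correlation). Of the latter, the ferritin chain Fth1 stood at -0.55 and the peroxidase Gpx4 at -0.56. Cell cycle genes were lower in 23 of 27 (adjusted p = 9.19e-04; adjusted p = 0.47 with an estimated correlation), germline genes in 9 of 11 (0.00291; adjusted p = 0.461 with an estimated correlation) and p53 targets in 14 of 19 (0.048; adjusted p = 0.555 with an estimated correlation).

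Oxidative phosphorylation, oxidative stress and cell cycle lists moved with the brightness of the arrays, and glycolysis did not. Endothelial and blood markers, a list called higher with the donor, were parted the other way. Their list mean was -1.817 to -1.46 on the 3 brighter arrays and -2.549 to -1.823 on the other 6. Fibroblast markers, not called, were parted that way too. After quantile normalization cell cycle had an adjusted p = 0.406 (median -0.15). The list mean of oxidative phosphorylation was 3.49 to 3.79 on the 3 brighter arrays, 2 of them with the donor and 0 without LIF alone, and 4.05 to 4.52 on the other 6. For oxidative stress and NRF2 genes the ranges were 2.32 to 2.51 and 2.92 to 3.22. For cell cycle genes they were 2.627 to 2.855 and 2.862 to 3.215, which barely part. For glycolysis they overlapped, at 2.16 to 3.1 and 2.2 to 3.6. Each list mean is relative to the mean of all genes tested on its array. The median log2 signal of the tested probe sets was 5.97 to 6.09 on the 3 brighter arrays and 5.56 to 5.85 on the other 6. A lower mean on the brighter arrays is thus partly built into the measure for lists of high signals. With brightness as a block, the adjusted p at the preset correlation was 0.00723 for oxidative phosphorylation (median -0.26), 0.0987 for oxidative stress (-0.3), 0.19 for cell cycle (-0.16) and 7.41e-08 for glycolysis (median -0.77). None of the brighter arrays is from cells without LIF alone, so this block rests on LIF replicate 1 and on donor replicate 3, an array of the alike pair. The glycolysis median was -0.17, -0.94 and -1.22 at passages 31, 33 and 34. Its list mean on no LIF replicate 1, 2.197, lay within the range of the donor arrays, 2.164 to 2.483. The shift thus rests on no LIF replicates 2 and 3, at 3.52 and 3.6.

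**Figure D4:**
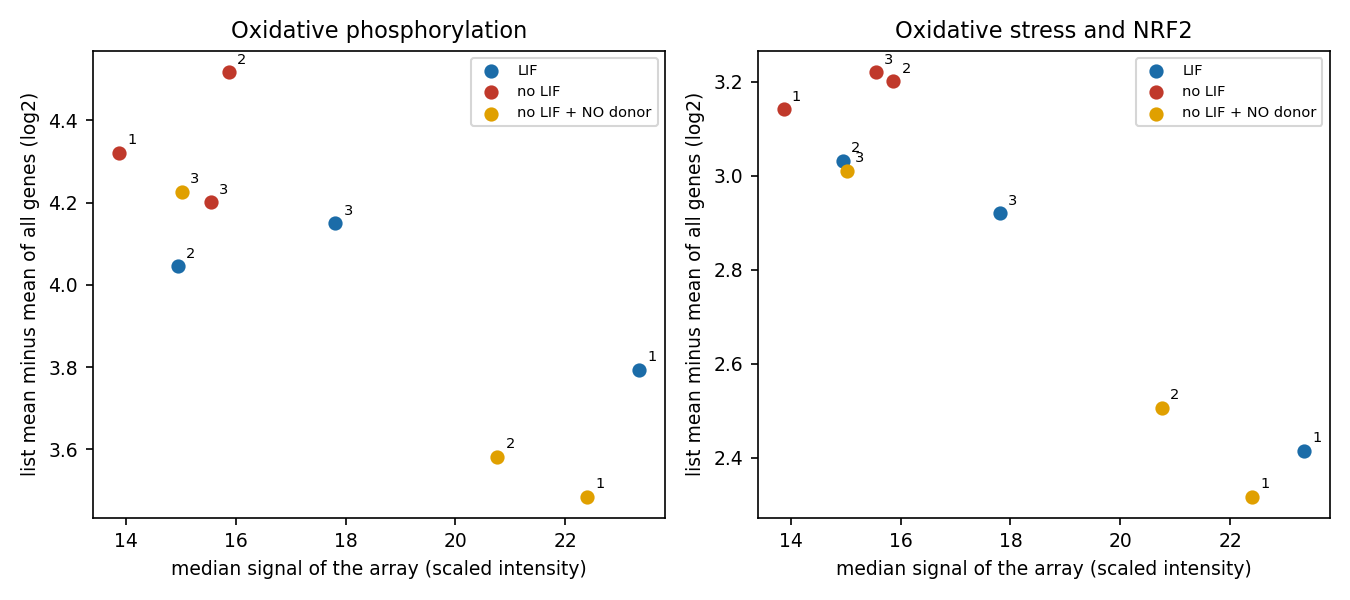
Mean log2 signal of 2 gene lists relative to all genes tested (vertical axis) against the median signal of each array in scaled intensity units (horizontal axis); points are arrays coloured by group and numbered by replicate. The 3 arrays with a median of 20.8 or more have the 3 lowest means of both lists. The mean of all genes is subtracted, so part of this fall is built in for lists of high signals.

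Of the 26 lists, 4 lay higher with the donor. Primitive streak and mesendoderm markers were higher in 17 of 18 with a median of 0.84 (adjusted p = 0.00235; adjusted p = 0.47 with an estimated correlation), Eomes standing at 0.7, with the opposite sign in its 1 other probe set, and Fgf17 at 1.27. Primed epiblast markers were higher in 15 of 17 with a median of 0.67 (adjusted p = 9.19e-04; adjusted p = 0.47 with an estimated correlation). WNT targets were higher in 10 of 11 (0.00546; adjusted p = 0.461 with an estimated correlation) and endothelial and blood markers in 13 of 14 (0.048; adjusted p = 0.47 with an estimated correlation). The nitric oxide and cGMP pathway had 8 of 17 members higher (adjusted p = 0.996), with Adh5, which clears S-nitrosoglutathione, at -0.66 and Vasp at -0.33. At passages 31, 33 and 34 the median was -2.35, 2.13 and 2.16 for streak markers and -0.53, 2.23 and 0.92 for primed markers, so passage 31 went the other way. For germline genes it was 0.03, -1.62 and 0.01. Without both replicate 2 arrays the primed list had an adjusted p = 0.671 with a median of -0.04, and the streak list 0.098 with 0.23. Endothelial markers had 0.183 (median 0.18) after quantile normalization, 0.904 (-0.07) with brightness as a block and 0.127 (0.41) without the alike pair, and p53 targets had 0.317 (-0.4), 0.789 (0) and 0.0921 (-0.47). After quantile normalization 9 lists passed in this comparison, so some lists not called in the main fit were gained there. Leaving out 1 array moved Socs3 to between -2.54 and -0.11, Fgf5 to between 0.29 and 3.89, Nanog to between -1.09 and -0.23, Pou5f1 to between -1.41 and -0.58, Fgf17 to between 0.79 and 1.62 and Gpx4 to between -0.83 and -0.37. Naive pluripotency (8 of 29 higher), LIF/STAT3 targets (9 of 19 higher) and the other 13 lists had an adjusted p from 0.0726 to 0.996. The median and the test took opposite signs for parietal endoderm (median -0.08) and anti-apoptotic genes (0.09).

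Limma called 0 of 29811 probe sets, with 1498 at an unadjusted p under 0.05 (5.02%, 1265 higher and 233 lower) and a smallest adjusted p of 0.929; called members of the lists were 0 over all genes and 0 adjusted over the list alone. The 1498 became 767 or 932 without no LIF replicate 2 or 3 and 454, 648 or 4219 without donor replicate 1, 2 or 3, and the 10 lists became 6 without donor replicate 2. With array brightness as a block the 1498 became 676.

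The third comparison sets cells with the donor against cells with LIF, and asks how near the donor brings cells to the LIF state. No gene passed the test. Fgf5 read 231 ± 292 with the donor and 19.4 ± 32.2 with LIF (SD, n = 3), a log2 difference of 3.79 (SE 1.69; limma adjusted p = 1), and was higher in 3 of 3 passages. Socs3 differed by -2.77 (SE 1.19), Gata6 by -1.7 (SE 0.66), Tbx3 by -1.55 (SE 0.88), Klf4 by -1.53 (SE 0.86) and Stat3 by -1.33 (SE 0.6). Pou5f1 differed by -0.16 (SE 0.41), Sox2 by -0.28 (SE 0.36), Nanog by -0.32 (SE 0.49), Zfp42 by -0.52 (SE 0.37) and Esrrb by -0.95 (SE 0.72). Of 3 other probe sets of Stat3, 2 took its sign.

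Among the 10 genes with the smallest p, Kcnh8, a potassium channel subunit, read 19 ± 3.14 with the donor and 0.847 ± 0.225 with LIF (SD, n = 3), a log2 difference of 2.51 (SE 0.46). The higher mean of Kcnh8 is within the array medians of 13.9 to 23.3, so it too is a dim signal. Sgip1 was at 1.79. Il27ra, Sycn, Grik4, Klhl10, Neurod2, Ptprcap, Alppl2 and Hnrnpl stood at -2.31 to -1.45, and the 1 other probe set of Hnrnpl took the opposite sign.

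Primed epiblast markers were higher with the donor in 15 of 17 members, with a median of 1.17 (adjusted p = 2.26e-09; adjusted p = 0.517 with an estimated correlation). Dnmt3b, a DNA methyltransferase of the epiblast, stood at 1.59 and Nodal at 0.23, with the opposite sign in the 1 other probe set of Nodal. Primitive streak markers were higher in 12 of 18 with a median of 1.04 (adjusted p = 0.00317; adjusted p = 0.517 with an estimated correlation). Of the lists, 6 lay lower: primitive and parietal endoderm in 16 of 19 (median -1.21, adjusted p = 5.84e-06), LIF/STAT3 targets in 15 of 19 (-0.69, 1.38e-04), hypoxia and glycolysis in 22 of 23 (-0.31, 1.38e-04), naive pluripotency in 21 of 29 (-0.32, 0.00317), Hox genes in 9 of 10 (-0.58, 0.00317) and oxidative phosphorylation in 21 of 26 (-0.22, 0.00428). With an estimated correlation the adjusted p was 0.526 for oxidative phosphorylation and 0.517 for each of the other 5. The Hox list again rests on 10 genes of dim signal. The naive list's brightest members were Dppa5a at -0.32 and Tdgf1 at -0.66, and among the STAT3 targets Icam1 stood at -1.32 and Pim3 at -0.5. Without the alike pair naive pluripotency had an adjusted p = 0.108 (median -0.26), the streak list 0.152 (0.45) and Hox genes 0.14 (-0.47). The primed, parietal endoderm and STAT3 lists passed there too, at 1.41e-06, 0.00679 and 0.0495, with medians of 0.99, -0.67 and -0.37. Without both replicate 2 arrays Hox genes had 0.438 (-0.33) and oxidative phosphorylation 0.0762 (-0.25). At passages 31, 33 and 34 the median was -0.07, 0.12 and 2.41 for streak markers and -0.83, 0.2 and -0.83 for glycolysis. It was -0.49, -0.16 and -2.54 for parietal endoderm, so passage 34 carried most of that shift. The parietal endoderm list mean was 2.32 on LIF replicate 3, against 1.14 and 0.855 on LIF replicates 1 and 2. For STAT3 targets the median was -0.81, -0.01 and -1.58, and for primed markers 1.51, 0.27 and 1.71. Leaving out 1 array moved Icam1 to between -2.09 and -0.36, Dnmt3b to between 0.74 and 2.24, Tdgf1 to between -1.19 and -0.3, Tbx3 to between -2.12 and -0.64, Esrrb to between -1.4 and -0.41 and Klf4 to between -2.14 and -0.88. The other 18 lists had an adjusted p from 0.0546 to 0.917. The median and the test took opposite signs for cardiac muscle (median 0.06), neuroectoderm (-0.06) and fibroblast markers (-0.06).

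Limma called 0 of 29811 probe sets, with 578 at an unadjusted p under 0.05 (1.94%, 317 higher and 261 lower) and a smallest adjusted p of 1; called members of the lists were 0 over all genes and 0 adjusted over the list alone. The 578 became 1091 or 248 without LIF replicate 2 or 3 and 354 or 990 without donor replicate 2 or 3, the 8 lists became 5 without LIF replicate 3, and with array brightness as a block oxidative phosphorylation had an adjusted p = 0.519 (median -0.13 against -0.22).

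Probe sets whose groups did not overlap made up 7.6%, 8.92% and 5.98% in the 3 comparisons, where chance gives 10%. The comparisons against LIF shared 0 calls, against a mean of 0.01 in 100 simulated sets of unchanged groups and 0 for independent lists. As each of them called 0, the shared count could only be 0 and tests nothing. At an unadjusted p under 0.05 in both, 47 probe sets shared a direction. The mean was 385.2 in the simulated sets, whose probe sets vary independently. The donor arrays were placed between LIF (0) and no LIF (1) on 200 genes chosen in the other passages, and the position was 0.643, 0.101 and 9.14 in passages 31, 33 and 34 (mean 3.29, SD 5.07, n = 3; exact sign-flip p = 1, smallest possible 0.25). The axis itself did not carry over: the signed mean of no LIF minus LIF was -0.754, -2.18 and 0.082 in the passage left out, so these positions place nothing.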

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

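The tests of array brightness and of passage 33, and all tests of the alike pair, were chosen after the result was seen. The prediction on exchanged labels and those on splits were written before any split was fitted, when the Socs3 signals, the array correlations and the sign of replicate 2 were already known.

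Genes of the fixed set whose difference took opposite signs in different passages are listed here; each passage has 1 array per group, so the differences between passages were not tested. Signs of 3 values differ by chance in 75% of cases, and they did for 10 of 11 genes in no LIF against LIF, 10 of 11 in the donor against no LIF and 4 of 11 in the donor against LIF. Log2 differences at passages 31, 33 and 34 follow. No LIF minus LIF: Nanog (-0.22, 1, 0.63), Sox2 (-0.73, 0.91, -0.39), Klf4 (-3.63, 1.26, -1.41), Zfp42 (0.28, 0.06, -1.1), Esrrb (-2.76, 1.29, -0.32), Tbx3 (-3.57, 0.25, -1.56), Socs3 (-4.94, 3.42, -2.43), Stat3 (-2.6, 1.04, -1.04), Fgf5 (7.07, -4.06, 2.58) and Gata6 (-1.64, 0.72, -3.62). Donor minus no LIF: Pou5f1 (-1.74, -1.22, 0.29), Nanog (-0.18, -2.29, 0.1), Sox2 (0.54, -0.93, -0.26), Klf4 (2.78, -2.02, -1.57), Zfp42 (0.11, -1.15, 0.25), Esrrb (2.13, -1.57, -1.62), Tbx3 (3, -0.86, -1.91), Stat3 (1.16, -2.15, -0.39), Fgf5 (-3.48, 4.58, 4.69) and Gata6 (0.34, -1.04, 0.14). Donor minus LIF: Pou5f1 (-0.83, -0.35, 0.7), Nanog (-0.4, -1.29, 0.73), Zfp42 (0.39, -1.09, -0.86) and Socs3 (-5.02, 0.52, -3.79).

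Socs3, Klf4, Stat3 and Fgf5 differed between no LIF and LIF in one direction at passages 31 and 34 and in the other at passage 33. After quantile normalization genes chosen in replicates 1 and 3 still had a signed mean of -2.212 in replicate 2. That step left 2194 calls in the split of the 3 brighter arrays from 3 dimmer ones, so it does not remove all that sets them apart. A difference in brightness between the 2 replicate 2 arrays is argued against, since their median signals were 14.95 with LIF and 15.87 without. A candidate explanation is that the labels of the 2 replicate 2 arrays were exchanged: with them exchanged, 4562 probe sets had an unadjusted p under 0.05, the most of the 10 splits (459 as labelled, next 2356), and 97 were called in place of 0. That replicate 2 ran the other way was already known, and exchanging its arrays raises the count whatever the cause. The count thus does not tell exchanged labels from a different response at passage 33. Some values kept 1 sign at passages 31, 33 and 34 as labelled: Pou5f1 (0.91, 0.87, 0.41), oxidative phosphorylation (0.43, 0.4, 0.1), cell cycle (0.3, 0.41, 0.24) and ERK targets (-0.48, -0.69, -0.46). They were picked for that, while 10 of 11 genes of the fixed set took opposite signs, where chance gives 75%. Oxidative phosphorylation and cell cycle also followed array brightness. These values therefore do not decide on an exchange. That cultures of passage 33 responded the other way stays open, because only 1 pair of arrays of that passage exists here, and no result of the comparisons uses exchanged labels.

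No LIF replicate 1 and donor replicate 3 had nearly the same signals. The SD of their log2 difference was 0.37 of that of the next closest pair, and 0.36 after quantile normalization. A like brightness as the cause is argued against by LIF replicate 2 and donor replicate 3. These were nearer in median signal, at 14.95 and 15.02, than no LIF replicate 1 at 13.87 and donor replicate 3. Their SD was 0.623, against 0.198 for the alike pair. That donor-treated and untreated cells do not differ would not bring 2 arrays this close, since the closest pair of 1 group had an SD 3.04 times as large; whether the donor has an effect stays open, as same-passage pairs of donor and no LIF arrays (0.786 to 1.33) overlapped pairs of 1 group (0.601 to 1.27). A candidate explanation is that both arrays measured 1 RNA or culture, in which case donor replicate 3 or no LIF replicate 1 is not a separate sample of its group. The poly-A spike Dap read 722 and 881 on the 2 arrays, and no other biological explanation was tested.

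For each comparison all 10 splits of its 6 arrays called as many probe sets as the real one, which called 0, and 10 splits are too few for a share under 0.05. The highest other count was 97 for no LIF against LIF, 0 for the donor against no LIF, and 2828 for the donor against LIF. For the donor against no LIF, the split that exchanges no LIF replicate 2 with donor replicate 3, and so sets the alike pair on 1 side, gave 5075 probe sets at an unadjusted p under 0.05, against 1498 as labelled. The split with 2828 parts LIF replicate 1 and donor replicates 1 and 2, the 3 brighter arrays, from the other 3, and it gave 2194 after quantile normalization. Counts of that size point to a structure of the arrays that the groups do not follow. Whether it lies in the samples or in how the arrays were made was not tested. With brightness as a block the donor and LIF differed in 0 calls, with 1653 at an unadjusted p under 0.05.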

How the results depend on the processing

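Fits with brightness as a block, on the 6 dimmer arrays or without doubted arrays were chosen after seeing the data; the rest were planned. limma called 0 probe sets in each comparison under every alternative, shared calls stayed at 0, and adjusted p reached no lower than 0.21 among the named genes when 1 array was left out. Without both replicate 2 arrays of LIF and no LIF the counts at an unadjusted p under 0.05 were 2326, 960 and 1297, and without the alike pair 738, 3440 and 1118. Lists called fell from 14, 10 and 8 to 0, 0 and 0 with an estimated correlation, and fry also called 0, 0 and 0. The estimate widens the test only where it exceeds the preset, as it did for 24 of the 26 lists, with a median of 0.154. If these estimates hold, the p-values at the preset correlation are too small for those lists. Leaving out 1 array gave 6 to 11 lists for the donor against no LIF and 5 to 9 for the donor against LIF. The mean position was -4.188 with no filter, where its denominator in passage 34 was -0.017. Deviations of same-numbered arrays from their group means had a mean r of -0.11, against 0.06 for other numbers. Of 9 such pairs 3 were over 0.1, LIF and donor replicate 1 reaching 0.65, and 3 of 9 arrays did best with their own number. Deviations cancel within a group, so the second mean nearly follows from the first. The alike pair also counts among the other numbers. These values thus do not settle whether arrays of 1 labelled passage vary together. With the replicate block limma called 0, 0 and 0 probe sets and 13, 10 and 9 lists. Of 83 named values, 66 kept their direction under every choice fixed before the data were seen. The 83 include the 10 genes with the smallest p of each comparison, which were chosen in these same data. None of those genes is among the 17 values that turned, so the 66 overstate how well directions held. Quantile normalization turned Cox4i1 with the donor against no LIF to 0.09, and median centring turned Sox2 and Pim3 without LIF to 0.15 and 0.17 and Tbx3 with the donor against no LIF to -0.15. Leaving out 1 array, no LIF minus LIF ranged from -1.3 to 0.2 for Esrrb, -0.1 to 3.5 for Fgf5, -1.74 to 0.4 for Icam1, -0.4 to 0.11 for Nodal, -0.39 to 0.4 for Pim3 and -0.45 to 0.14 for Sox2. Donor minus no LIF ranged from -0.09 to 1.83 for Eomes, -1.15 to 0.34 for Esrrb, -0.5 to 0.32 for Gata6, -1.18 to 0.65 for Klf4, -0.42 to 0.16 for Sox2, -0.92 to 0.13 for Stat3 and -0.82 to 0.99 for Tbx3. Donor minus LIF ranged from -0.62 to 0.24 for Nanog, -0.04 to 0.65 for Nodal and -0.69 to 0.15 for Pou5f1. Leaving out 1 array moved 16 of 27, 15 of 29 and 14 of 27 named values of the 3 comparisons by over 1.5 times. The cause of these moves was not tested. Where an omission left a group with 1 array, that array was assumed to vary like the others.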

Other observations

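All tests in this part were chosen after the list means of the arrays had been seen.

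Across the 9 arrays, whatever their labels, the means of several fixed lists followed that of the naive pluripotency list. Of 25 relations tested, LIF/STAT3 targets gave Pearson's r = 0.92 (exact permutation p = 4.38e-04, adjusted 0.011) and Spearman's rho = 0.97 (exact p = 1.65e-04, adjusted 0.00413). Primed epiblast markers gave r = -0.89 (exact p = 0.00206, adjusted 0.0258) and rho = -0.87 (exact p = 0.00451, adjusted 0.0225). Primitive streak markers gave r = -0.91 (exact p = 0.00384, adjusted 0.0319) and rho = -0.9 (exact p = 0.00203, adjusted 0.0169). Without the 2 arrays farthest from the median, no LIF replicate 2 and LIF replicate 1, r was 0.87, -0.77 and -0.86. Visceral endoderm gave r = 0.85 (exact p = 0.00798, adjusted 0.0399; rho = 0.88, exact p = 0.00308) and parietal endoderm r = 0.74 (exact p = 0.0114, adjusted 0.0475; rho = 0.92, exact p = 0.00131), with 0.83 and 0.86 without those arrays. Cardiac muscle markers gave r = -0.82 (exact p = 0.0051, adjusted 0.0319) but rho = -0.63 (exact p = 0.076) and -0.6 without those arrays. The nitric oxide and cGMP pathway passed by rank only, with rho = 0.83 (exact p = 0.00827, adjusted 0.0344) and r = 0.72 (exact p = 0.0176, adjusted 0.0629). Among the 6 dimmer arrays, which hold both arrays of the alike pair, r was 0.98 for STAT3 targets (exact p = 0.00556), -0.99 for primed markers (exact p = 0.0111) and -0.89 for streak markers (exact p = 0.00833). It was 0.88 for visceral endoderm (exact p = 0.0528), 0.79 for parietal endoderm (exact p = 0.075) and -0.73 for cardiac muscle (exact p = 0.133), which did not pass there. The 3 brighter arrays are too few for a value. The p-values of the dimmer arrays are not adjusted, and all p-values here count the alike pair as 2 separate arrays. With that pair averaged, r across all arrays was 0.9 for STAT3 targets, -0.87 for primed markers and -0.89 for streak markers. It was 0.82 for visceral endoderm, 0.68 for parietal endoderm and -0.84 for cardiac muscle.

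The naive and primed lists ran against each other from array to array. A relation carried by the 3 brighter arrays is argued against, since r was -0.99 within the 6 dimmer ones. After quantile normalization r was -0.77, but that step does not remove all that sets the brighter arrays apart. A relation carried by the alike pair is argued against too, since r was -0.87 with those 2 arrays averaged. The labels as given do not order the arrays, because 2 arrays outside the LIF group had a naive mean above the lowest LIF array. With the labels of the 2 replicate 2 arrays exchanged, 0 arrays outside the LIF group lay above its lowest array (3.14 to 3.39 with LIF, 3.1 at most elsewhere), but 1 did after quantile normalization (donor replicate 1 at 3.37, LIF replicate 3 at 3.14), so exchanged labels are not settled as an account of this order. Whether the cultures otherwise differ in how far they had left the naive state was not tested.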
